A study of Homo sapiens with 6 samples.

How the data were processed

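RNA from 6 PC3 cultures was sequenced, 3 transfected with siScr and 3 with siAZIN1 on day 1 after plating and harvested between 48 and 72 hours later, per the labels' protocols. Total RNA was extracted on RNeasy columns and libraries followed standard Illumina protocols, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the columns of the count table were matched to samples through the sample descriptions.

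The deposited count table holds unnormalised whole-number read counts for 58828 gene symbols in each library, and TopHat, HTSeq and DESeq with the builds GRCh37 and hg19 are named, with no versions or roles, per the submitters' processing notes. The annotation release and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes, and near-identical genes such as histones, are therefore uncertain where reads could be shared. A second deposited table gives the authors' comparison. Its fold column is the ratio of mean normalised counts in group B over group A, per the file headers. Its log2 column is the log2 of that ratio, per the file headers. Its p-value and adjusted p-value columns are the authors' test results, per the file headers. Dividing the counts by median-ratio size factors gave the authors' log2 fold change of siAZIN1 over siScr to within 3.73e-10 for 23265 genes, so that group B is siAZIN1. No row of the count table is a total or an unassigned class.

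Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14386 of 28339 genes with any count, libraries were scaled by TMM, and glmQLFit and glmQLFTest compared the groups with no covariate, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size over the square root of the F statistic. CPM values use TMM-scaled library sizes. The total counts ranged from 6671098 to 20511036 per library, so that siScr replicate 1 gives the least precise values of low genes. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of at least 2.49 over genes with 10 or more counts in a pair), and each was counted as a replicate.

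Before the data were examined, the test, the 33 gene lists, the rule for named genes and all alternatives not marked here as added were fixed. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, a minimum of 5 tested genes and Benjamini-Hochberg adjustment over the 32 lists that reached it. Of 1312 list entries, 1304 were matched to a symbol of the table, directly or by an unambiguous synonym in the RefSeq gene table. The lists cover polyamine metabolism, cell cycle, ribosome, stress, interferon, cytokine, matrix, adhesion, lipid, energy, prostate lineage and other cell types, and each has its result in the text. The named genes are AZIN1, 9 polyamine genes whatever their result, the 5 genes with the smallest p, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, and from each list up to 4 called members with the smallest p, or the 1 with the smallest p where none was called. Some were left out for length, and others are not reported here.

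Alternatives were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each of the 6 libraries, and for the lists an estimated correlation and fry. Added after the data were seen were robust empirical Bayes, voom with quality weights, the estimated correlation without siScr replicate 1, and lists without genes that carry the sequence CATAGCA. Other splits of the 6 libraries were fitted with edgeR.

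For sequence tests, the longest 3′ untranslated region among protein-coding transcripts of GENCODE v29, annotated on another genome build than the counts, was joined by gene symbol, and no coordinates were used. It was found with at least 50 bases for 12283 genes other than AZIN1. For each of 16232 sequences of 7 bases (7-mers) carried by at least 50 genes, a linear model of the signed normal score of each gene's edgeR p on carrying the 7-mer, with length, GC content and 2 Alu sequences as covariates, gave a t value, and p was adjusted by Bonferroni. The Alu terms were added after a first scan. Sites of 39 microRNA families, 26 classed as broadly expressed and 13 as restricted to other tissues, were taken from textbook seed sequences. No microRNA was measured, so the classes do not show which families these cells express. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 was used.

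The tests were tested on simulated data. In 6 draws of counts with the means, sizes and dispersions of this comparison over 14386 genes, each with 200 changed genes, edgeR recovered 72.2% of genes changed 1.5-fold and 84.3% of those changed 2-fold, and 8.12% of its calls were false, above the 5% aimed at. Camera called the 1 list lowered by simulation and no other. The simulated genes varied independently of each other. That result therefore does not test the preset correlation on lists whose genes vary together. A planted 7-mer effect, a shift of −0.8 in the score, came out strongest in 10 of 10 runs over 12283 genes. With no planted effect a 7-mer passed Bonferroni in 1 of 10 runs. The scores were shuffled among genes in these runs. They therefore do not test weaker effects, or false calls where fold changes vary with length, GC content or shared regulation.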

Results

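Transcript abundance was measured by RNA sequencing in PC3 cells, an established line from a human prostate cancer metastasis, after transfection with a small interfering RNA (siRNA) against AZIN1 (siAZIN1) or with a scrambled control siRNA (siScr). AZIN1 encodes antizyme inhibitor 1, a protein that binds antizyme and thereby spares ornithine decarboxylase, the first enzyme of polyamine synthesis, from degradation. Each group held 3 libraries, described in the series design as biological replicates. How the replicates were made is not stated further, so the p-values measure the spread between these libraries. The total count was 6671098 in siScr replicate 1, 16341499 in siScr replicate 2 and 20511036 in siScr replicate 3. In the siAZIN1 libraries it was 19864223, 19230091 and 19620094. After the low-count filter, 14386 genes were tested.

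The comparison asked which transcripts differ when AZIN1 is silenced. AZIN1 itself fell in all 3 siAZIN1 libraries. Its normalised level was 451, 439 and 425 CPM (counts scaled to a common library size) in siScr replicates 1, 2 and 3 and 41.7, 37.1 and 42.5 CPM in siAZIN1 replicates 1, 2 and 3. The group means were 438 ± 13.3 and 40.4 ± 2.92 CPM (SD, n = 3 each), a 10.8-fold fall. On the log2 scale the change was −3.44 with a standard error (SE) of 0.071, and the adjusted p was 1.91e-10 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, which is used for all gene-level p-values here unless another test is named.

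Knockdown went with many small changes. Of the 14386 genes, 3050 passed an adjusted p of 0.05, 1465 higher and 1585 lower in siAZIN1, but only 85 of them changed at least 2-fold. Without siScr replicate 1, the shallowest library, 4054 genes passed, of which 123 changed at least 2-fold. Counts fell by over 1.5 times when siScr replicate 2 (1910 genes), siScr replicate 3 (1880 genes) or siAZIN1 replicate 3 (1735 genes) was left out.

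After AZIN1, the smallest p-values belonged to VPS4B, an ATPase that disassembles the membrane-remodelling ESCRT complex, KCTD2, ANKRD52, a regulatory subunit of a protein phosphatase, and TCEAL4. VPS4B was 2.30-fold lower (log2 change −1.20, SE 0.045, adjusted p = 7.63e-08 by edgeR). KCTD2 was 2.26-fold lower and TCEAL4 2.16-fold lower, while ANKRD52 was 2.14-fold higher (group mean 198 CPM in siAZIN1). The largest changes were ranked among called genes with a mean of at least 5 CPM and no overlap between the groups. Rises included PLEKHH1 (2.59-fold, with low group means of 5.83 CPM in siScr and 13.9 CPM in siAZIN1) and the tight-junction gene CLDN11 (2.17-fold). The collagen genes COL5A1 (2.15-fold) and COL4A2 (1.97-fold) and the guanine nucleotide exchange factor gene RAPGEF1 (2.08-fold) were also among them. Among the largest falls were NOX5, an NADPH oxidase (2.69-fold), CHSY3, a chondroitin synthase (2.45-fold), SCIN, an actin-severing protein (2.35-fold), and CCNA1, a cyclin (2.32-fold). The 3′ untranslated regions of KCTD2, TCEAL4, NOX5, CHSY3 and SCIN among these falls and of ANKRD52, PLEKHH1, COL5A1 and COL4A2 among the rises, like those of 46.4% of genes, hold at least 1 of 7 short sequences that also occur in an AZIN1 transcript and went with lower fold changes across genes. Those of VPS4B, CCNA1, CLDN11 and RAPGEF1 hold none. The sequence TGGTGCT, which went with higher fold changes, was held by 16.9% of genes, among them ANKRD52, COL5A1, RAPGEF1 and COL4A2.

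**Figure D1:**
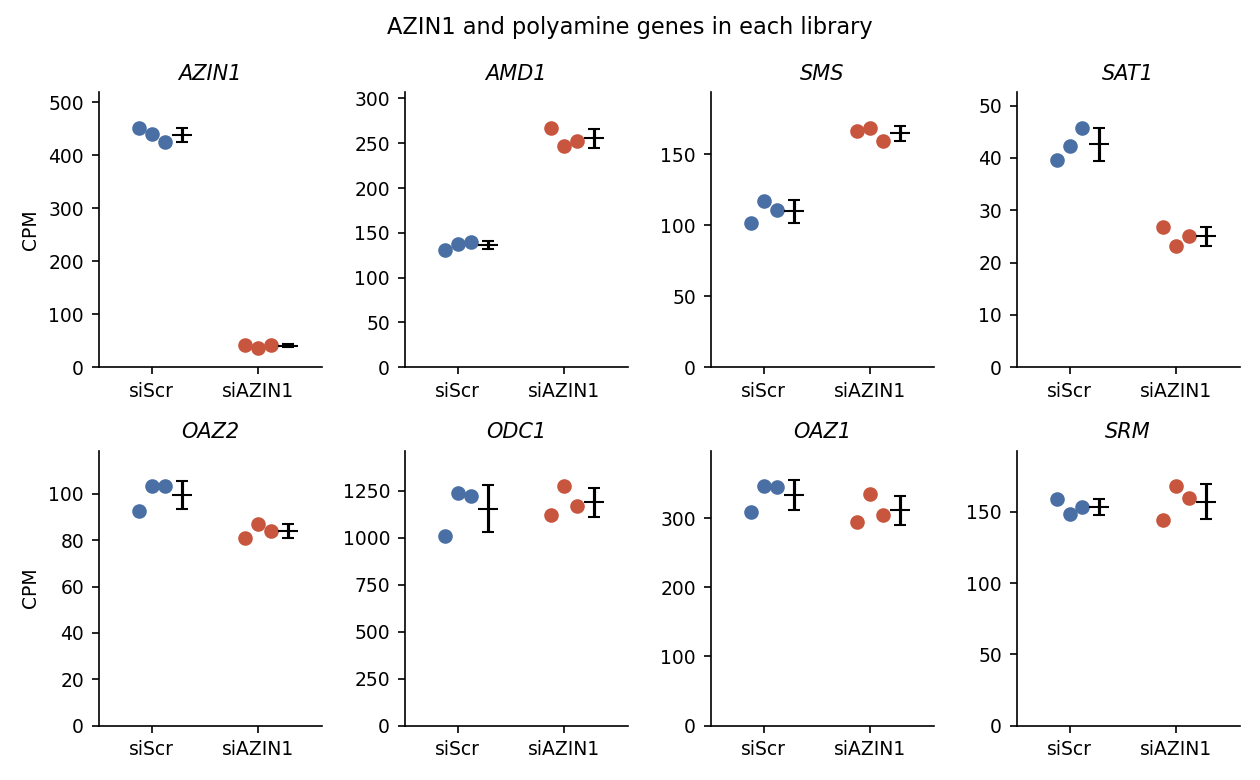
Normalised level in CPM (y axis, linear, from 0) of AZIN1 and 7 genes of polyamine metabolism in the siScr (blue) and siAZIN1 (red) libraries; points are the 3 libraries of each group and the bar beside them is the mean ± SD. AMD1 and SMS lie higher and AZIN1, SAT1 and OAZ2 lower in siAZIN1, whereas ODC1, OAZ1 and SRM did not pass the test.

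Genes of polyamine metabolism changed in both directions. AMD1, which makes the aminopropyl donor for spermidine and spermine synthesis, rose 1.87-fold (log2 change 0.91, SE 0.057, adjusted p = 2.66e-06 by edgeR), and SMS, spermine synthase, rose 1.49-fold (log2 change 0.58, SE 0.057). SAT1, which acetylates spermidine and spermine for export or breakdown, was 1.72-fold lower (log2 change −0.78, SE 0.078), ENOPH1, of the methionine salvage pathway, 1.30-fold lower, and OAZ2, an antizyme, 1.19-fold lower. ODC1, the enzyme that AZIN1 protects, had a log2 change of 0.04 (SE 0.081, adjusted p = 0.773), and OAZ1, the main antizyme, one of −0.10 (SE 0.071, adjusted p = 0.367, but 0.0289 by limma-voom with quality weights). AZIN2, SRM and SMOX did not pass either, with adjusted p-values of 0.844, 0.737 and 0.985 by edgeR. Of the 27 members of the polyamine list, 6 rose, 6 fell and 15 did not pass, and 6 rose and 8 fell when adjusted over the list alone. As a set they did not move one way (camera, adjusted p = 0.527).

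Genes of the G1/S transition and DNA replication fell together. Of 50 members, 42 were lower, none was higher and 8 did not pass (45 lower when adjusted over the list alone; 0 were higher by edgeR at an unadjusted p under 0.05, by DESeq2 or by limma-voom), with a median log2 change of −0.41, and camera gave an adjusted p of 1.58e-21. That call was lost with the correlation estimated from the data (adjusted p = 0.276 with an estimated correlation). The cyclin gene CCNE2 was 2.04-fold lower, the replication clamp gene PCNA 1.39-fold lower, the thymidylate synthase gene TYMS 1.49-fold lower and the chromatin assembly gene CHAF1B 1.46-fold lower, with SEs of 0.045 to 0.090 on the log2 scale. Of the lower genes named in the gene groups, OAZ2, ENOPH1, CCNE2, CHAF1B, CCND1, TACC3, NEK2, SPRY4, DUSP4, MAFF, CXCL8, FN1, OCLN, ITGA1, TMPRSS2 and SYT1 hold 1 or more of the 7 short sequences, and so do the higher genes AMD1, COL4A2, COL4A1, NID1, CYR61, DLC1, AJUBA, PTPN14, INSIG1 and HMGCS1. Among them, ENOPH1, CHAF1B, CCND1, NEK2, DUSP4, FN1, OCLN, TMPRSS2, AMD1, NID1, CYR61, AJUBA and INSIG1 hold only the common TATTTAT. TGGTGCT is held by SMS, COL4A2, COL4A1, NID1, INSIG1 and HMGCS1, which rose, and by OCLN, which fell. Without siScr replicate 1, 44 members were lower and the median was −0.40.

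A smaller fall was seen in genes of G2/M and mitosis, of which 19 of 54 were lower (11 without siScr replicate 3 or siAZIN1 replicate 3), none was higher and 35 did not pass (21 lower when adjusted over the list alone; 0 were higher by edgeR at an unadjusted p under 0.05, by DESeq2 or by limma-voom, and 1 was higher without siScr replicate 1). BIRC5, a mitotic regulator and apoptosis inhibitor, was 1.45-fold lower (459 against 318 CPM in group means), TACC3, a spindle protein, 1.29-fold lower and NEK2, a centrosome kinase, 1.27-fold lower. Camera gave an adjusted p of 4.45e-06 (adjusted p = 0.790 with an estimated correlation and 0.0911 with fry). CCND1, the cyclin that drives entry into the cell cycle, was 2.31-fold lower (969 against 419 CPM in group means; log2 change −1.21, SE 0.058, adjusted p = 4.15e-07 by edgeR).

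CCND1 stands in the list of immediate early and growth factor response genes, in which 9 of 30 members fell, 2 rose and 19 did not pass (11 lower and 3 higher when adjusted over the list alone; 1 rose without siScr replicate 2, siScr replicate 3, siAZIN1 replicate 2 or siAZIN1 replicate 3). The feedback inhibitors SPRY4 (1.47-fold) and DUSP4 (1.38-fold) of the MAP kinase pathway and the transcription factor MAFF (1.46-fold) were lower too. The list passed with camera at an adjusted p of 0.00991 (adjusted p = 0.765 with an estimated correlation), but not without the genes that carry CATAGCA, 1 of the 7 short sequences (adjusted p = 0.06335). Interferon response genes also fell, 10 of 45, with 1 higher and 34 not past the test (10 lower and 1 higher when adjusted over the list alone). DDX58, the RNA sensor RIG-I, was 1.37-fold lower, OAS1 1.36-fold lower and ISG15 1.27-fold lower. The camera adjusted p was 0.00463 (adjusted p = 0.790 with an estimated correlation and 0.285 with fry), and it was 0.106 when siAZIN1 replicate 2 was left out. Without siScr replicate 3 or siAZIN1 replicate 3, 6 members were lower. The number higher was 3 without siScr replicate 1 and 0 without siScr replicate 2, siScr replicate 3 or siAZIN1 replicate 3.

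Genes of collagens and the extracellular matrix rose on balance. Of 56 members, 22 were higher, 3 were lower and 31 did not pass (22 higher and 4 lower when adjusted over the list alone), and the median log2 change was 0.16. Leaving out siScr replicate 1 gave 27 higher and 5 lower. COL4A2 and COL4A1, which encode chains of basement membrane collagen, rose 1.97-fold and 1.65-fold, and NID1, a basement membrane glycoprotein, 1.54-fold, whereas the laminin chain gene LAMA3 was 1.45-fold lower. Camera gave an adjusted p of 3.75e-06 (adjusted p = 0.790 with an estimated correlation and 0.0712 with fry). Targets of YAP and SRF, transcriptional regulators that respond to cell shape and the actin skeleton, rose as well, 12 of 35, with 2 lower and 21 not past the test (15 higher and 3 lower when adjusted over the list alone). The 2 lower became 0 without siAZIN1 replicate 3 and 1 without siScr replicate 2, siScr replicate 3 or siAZIN1 replicate 2. CYR61 rose 1.70-fold, DLC1 1.56-fold, AJUBA 1.38-fold and PTPN14 1.29-fold, and the camera adjusted p was 0.00012 (adjusted p = 0.765 with an estimated correlation).

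Cholesterol synthesis genes were higher in 12 of 27 cases, lower in 2 and not past the test in 13 (12 higher and 2 lower when adjusted over the list alone). INSIG1, a sterol-regulated inhibitor of the pathway, rose 1.75-fold (log2 change 0.81, SE 0.043, adjusted p = 8.19e-07 by edgeR). HMGCS1, an enzyme of early cholesterol synthesis, rose 1.61-fold. Camera gave an adjusted p of 5.1e-05 (adjusted p = 0.790 with an estimated correlation). The 77 cytosolic ribosomal protein genes had a median log2 change of 0.09 and passed with camera (adjusted p = 0.00108; adjusted p = 0.790 with an estimated correlation), but 0 of them passed the edgeR test singly or adjusted over the list alone. At an unadjusted p under 0.05, 8 were higher and 0 lower by edgeR, and 6 passed as higher with DESeq2 and 2 with limma-voom. RPL37, the member with the smallest p, had an adjusted p of 0.052 by edgeR and was among those that passed with the other tools. Without siScr replicate 1 that list had a median of 0.03 and a camera adjusted p of 0.544, with 1 member higher and 3 lower by edgeR. By edgeR 1 member was higher without siScr replicate 3 and 2 were without siAZIN1 replicate 1. Without siAZIN1 replicate 2 the camera adjusted p was 0.237, and with fry and all libraries the list's adjusted p was 0.555.

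**Figure D2:**
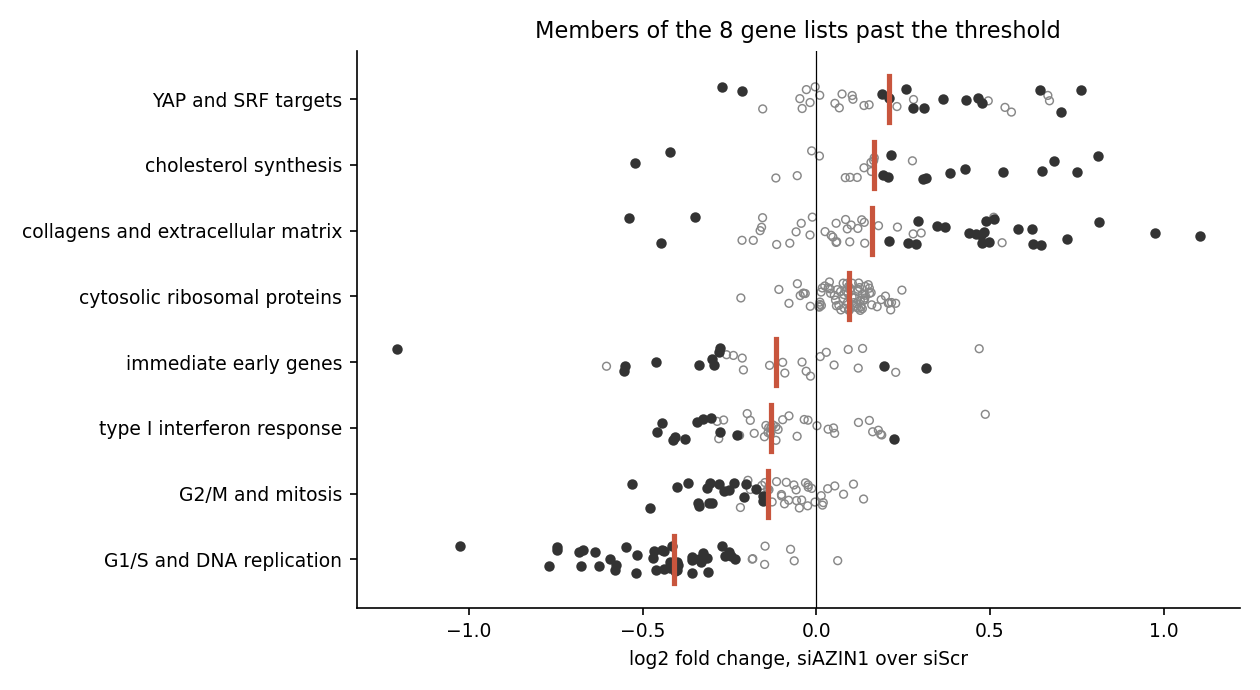
Log2 fold change of siAZIN1 over siScr (x axis) for each tested member of the 8 gene lists past the camera threshold (rows); filled points passed the edgeR test, open points did not, and the red bar is the list's median. The G1/S list has the lowest median, −0.41, and the YAP and SRF list the highest, 0.21.

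Cell adhesion and cytokine genes changed in both directions. In the list of integrins, focal adhesion and actin, 18 of 69 rose, 10 without siScr replicate 3 or siAZIN1 replicate 3, and 16 fell (19 and 18 when adjusted over the list alone), among them ITGA5, which rose 1.57-fold, and ITGA1, which was 1.61-fold lower. Among 40 genes of the epithelial-mesenchymal transition, 6 rose and 10 fell (6 and 15 when adjusted over the list alone). SNAI2, a transcriptional repressor of epithelial genes, rose 1.61-fold, FN1, fibronectin, was 1.36-fold lower and OCLN, occludin, 1.43-fold lower. Of 38 NF-kB targets and cytokines, 7 rose and 5 fell (7 and 9 when adjusted over the list alone; 9 fell without siScr replicate 1, 3 without siAZIN1 replicate 1 and 2 without siScr replicate 3 or siAZIN1 replicate 3). The chemokine gene CXCL6 rose 1.75-fold, whereas CXCL8 was 1.54-fold lower (83.6 against 55.5 CPM in group means). In the angiogenesis list 10 of 41 rose and 7 fell (14 and 9 when adjusted over the list alone). Without siScr replicate 1, 16 rose and 7 fell, and with any 1 of the other libraries left out 5 to 7 rose and 1 to 3 fell. Of 36 apoptosis regulators, 8 rose and 5 fell (10 and 5 when adjusted over the list alone; 4 rose without siAZIN1 replicate 3 and 5 without siScr replicate 2, siScr replicate 3 or siAZIN1 replicate 1). Camera adjusted p-values for these lists were 0.701, 0.269, 0.503, 0.0617 and 0.701. Camera looks for a shift in 1 direction, so it cannot tell whether members with opposed roles changed together. With change in either direction allowed, fry gave these lists unadjusted p-values of 3.1e-08 to 0.00011. The angiogenesis list passed without siScr replicate 1 (0.024), siScr replicate 3 (0.0368) or siAZIN1 replicate 1 (0.0283), at 0.0408 with a filter of at least 1 CPM in 3 libraries, and at 0.0492 with a replicate block. That call was lost with the correlation estimated from the data (adjusted p = 0.790 with an estimated correlation, 0.764 with it and without siScr replicate 1).

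None of the lists that mark prostate cell states and other cell types passed with camera when all libraries were used with the default filter. In the list of androgen receptor targets and luminal markers, 3 of 25 rose and 7 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.0715, 0.024 without siScr replicate 1 and 0.0408 with the CPM filter, but adjusted p = 0.790 with an estimated correlation and 0.641 with it and without siScr replicate 1), and TMPRSS2 was 1.24-fold lower. For basal epithelial markers the numbers were 1 and 4 of 13 (1 and 4 when adjusted over the list alone; camera adjusted p = 0.0993), and for neuroendocrine and neuronal markers 0 and 1 of 7 (0 passed when adjusted over the list alone, and 0 were higher by edgeR at an unadjusted p under 0.05, by DESeq2 or by limma-voom; camera adjusted p = 0.288). The 1 lower gene, SYT1, did not pass when any 1 library was left out; 2 other members of that list were lower without siScr replicate 1 and 0 members without any 1 of the others. Fibroblast and smooth muscle markers (7 tested, 1 higher and 1 lower; 2 and 1 when adjusted over the list alone) and endothelial markers (6 tested, 1 higher and 1 lower; 1 and 1 when adjusted over the list alone) had camera adjusted p-values of 0.256 and 0.689. In the basal and the fibroblast and smooth muscle lists, 2 markers each were higher without siScr replicate 1. The lower fibroblast or smooth muscle marker was not called without siScr replicate 2, siScr replicate 3, siAZIN1 replicate 1 or siAZIN1 replicate 3, nor the higher endothelial marker without siScr replicate 2. Of the leukocyte markers 2 were expressed enough to be tested, and neither passed by edgeR, at an unadjusted p under 0.05 or with DESeq2 or limma-voom; 1 was lower without siScr replicate 1.

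Among the controls, siScr replicate 1 stood apart. The 8 RNAs RN7SK, RMRP, RPPH1, SNORD3A, SNORA73B, MT-RNR1, MT-RNR2 and MIR663AHG, chosen after their values were seen, took 12.1% of its counts and 1.42% to 1.46% of those of the other 5 libraries. RMRP, MIR663AHG and MT-RNR1 rank by fold among the largest falls in siAZIN1. Their log2 changes were −7.80, −6.36 and −3.62 with all libraries and −0.43, −0.18 and −0.32 without it, where RMRP and MIR663AHG no longer passed (adjusted p of 0.0838 and 0.202 by edgeR). None of the 3 passed when any 1 siAZIN1 library was left out (adjusted p of 0.0636 to 0.106 by edgeR). AZIN1 in this library was at the level of the other controls.

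**Figure D3:**
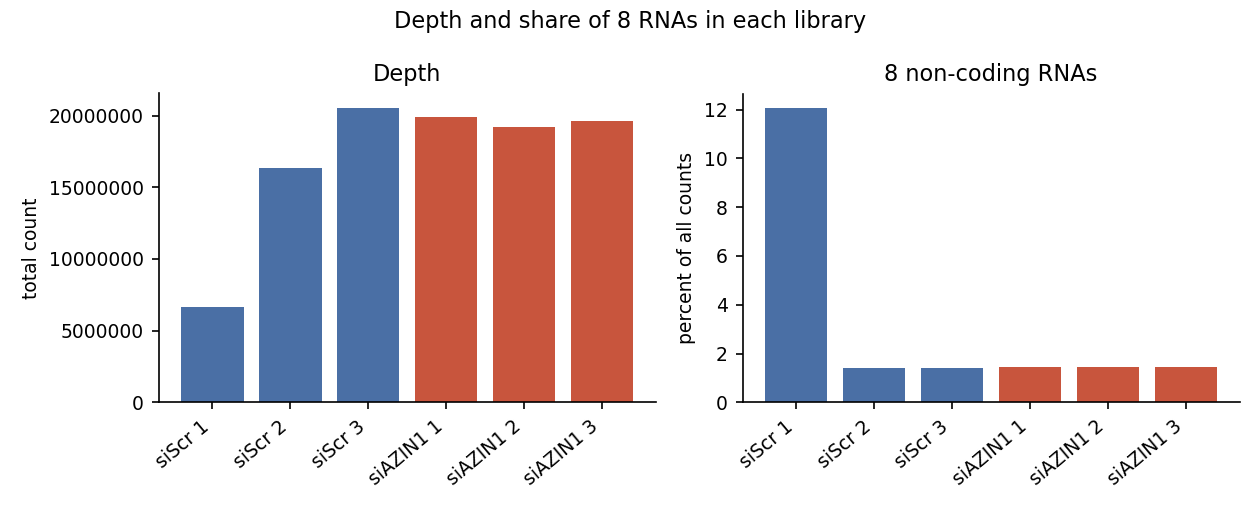
Total count (left, y axis) and the share of all counts, in percent, taken by 8 RNAs (right, y axis) in each siScr (blue) and siAZIN1 (red) library. The siScr replicate 1 library has the lowest total, 6671098, and the highest share, 12.1%.

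The authors' deposited table of the same comparison lists 1460 genes at an adjusted p under 0.05, 669 higher and 791 lower in siAZIN1. Of these, 1456 were among the 3050 genes called here, all with the same sign. Across 14386 genes, which are not independent replicates, the log2 fold changes in the authors' deposited table and those computed here had a Pearson correlation of 0.976.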

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

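Robust empirical Bayes, voom with quality weights, and the list tests without siScr replicate 1 under an estimated correlation or without carriers of CATAGCA were chosen after the data were seen. AZIN1 stayed lower and past the threshold in every setting run. The count of called genes, 3050, was 1735 to 4054 when single libraries were left out (806 to 1979 higher and 929 to 2075 lower; 61 to 123 changed at least 2-fold). It was 4982 with quality weights (2454 higher, 2528 lower) and within 1.5 times of 3050 in all other settings. Genes changed at least 2-fold numbered 201 with no low-count filter, which tests more low genes, and 47 with DESeq2, where the cause was not tested. Of 125 other called named genes, 113 kept their call and direction in all settings that gave them a value. The calls of RMRP and MIR663AHG and the size of the MT-RNR1 change rest on siScr replicate 1. Of 8 lists past the threshold, 0 passed with an estimated correlation, with or without siScr replicate 1 (smallest adjusted p 0.276 and 0.425). At an unadjusted p under 0.05, 1 and 3 lists passed, and the cause was not tested. With fry, which asks another question, 4 of the 8 passed: G1/S (adjusted p = 0.00607), immediate early (0.00667), YAP and SRF (0.0195) and cholesterol (0.0358). The matrix (0.0712), G2/M (0.0911), interferon (0.285) and ribosomal protein (0.555) lists did not pass with fry. The number of lists past camera was 7 to 11 when single libraries were left out. Without carriers of CATAGCA the immediate early list had an adjusted p of 0.06335 (0.00565 to 0.765 over its other alternatives). Same-numbered libraries had deviation correlations of 0.180, 0.211 and −0.028, and not every sample correlated best with its own number. Deviations of 3 libraries from their group mean depend on each other. These values therefore neither show nor exclude pairing, which the labels do not state. With a replicate block 3732 genes and 10 lists passed. Besides the 8 lists, these were the angiogenesis (camera adjusted p = 0.0492) and mitochondrially encoded (0.022) lists. Low depth in siScr replicate 1 limits what can be said of genes with few counts.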

Other observations

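Chosen after the result was seen were the tests of any of several 7-mers in the G1/S list, of the G1/S and matrix lists without siScr replicate 1, of microRNA families, of the miR-29 site in matrix genes, of overlap with AZIN1 transcripts beyond the strongest 7-mer and of 2 parts of the genes.

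Stress and metabolic genes changed in both directions in most lists. In the main camera test, with all libraries, the preset correlation and no replicate block, none of these lists passed. Of 31 p53 targets, 6 rose and 5 fell (7 and 5 when adjusted over the list alone, 3 higher without siAZIN1 replicate 3; adjusted p = 0.701). TP53INP1 rose 1.63-fold and SESN2, a stress-induced inhibitor of mTORC1, 1.62-fold, whereas GDF15, a stress-induced cytokine, was 1.47-fold lower. Among 36 genes of ATF4 and amino-acid stress, 5 rose and 6 fell (6 and 6 when adjusted over the list alone, 3 higher without siScr replicate 2, siAZIN1 replicate 2 or siAZIN1 replicate 3; adjusted p = 0.270), with PHGDH, of serine synthesis, 1.33-fold lower. Of 41 genes for chaperones and degradation in the endoplasmic reticulum, 0 rose and 5 fell by edgeR, HERPUD1 by 1.29-fold (0 and 5 when adjusted over the list alone; 3 were higher by edgeR at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom; adjusted p = 0.270). Of 32 antioxidant genes under NRF2, 1 rose and 6 fell (1 and 7 when adjusted over the list alone, 2 higher without siScr replicate 1 or siAZIN1 replicate 1, 3 lower without siScr replicate 3; adjusted p = 0.173), with SLC6A6, the taurine transporter, up 1.43-fold and MGST1 1.51-fold lower. Heat shock and proteostasis genes numbered 1 higher and 5 lower of 25 (2 and 6 when adjusted over the list alone; adjusted p = 0.288). Of these, 2 were higher without siScr replicate 1 or siAZIN1 replicate 1, and 2 lower without siScr replicate 2, siScr replicate 3, siAZIN1 replicate 1 or siAZIN1 replicate 3.

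In the list of MYC targets and ribosome biogenesis, 3 of 45 rose and 5 fell (2 and 5 when adjusted over the list alone, 1 higher without any 1 siAZIN1 library, 2 lower without siScr replicate 2 and 3 without siScr replicate 3, siAZIN1 replicate 1 or siAZIN1 replicate 3; adjusted p = 0.663), DDX21, a nucleolar RNA helicase, by 1.52-fold. For 29 TGF-beta and SMAD targets the numbers were 7 and 5 (7 and 5 when adjusted over the list alone, 4 higher without siScr replicate 2 or siAZIN1 replicate 3, 2 lower without siScr replicate 3 or siAZIN1 replicate 3 and 3 without siScr replicate 2 or siAZIN1 replicate 1; adjusted p = 0.616), with TGFBR2 up 1.43-fold and the cell cycle inhibitor CDKN2B 1.62-fold lower. Fatty acid genes gave 5 higher and 2 lower of 30 (5 and 2 when adjusted over the list alone, 2 higher without siAZIN1 replicate 3 and 3 without siScr replicate 2 or siAZIN1 replicate 2, 1 lower without any 1 library but siScr replicate 1; adjusted p = 0.179), and hypoxia and glycolysis genes 7 and 3 of 43 (7 and 3 when adjusted over the list alone, 7 and 8 without siScr replicate 1, 4 higher without siAZIN1 replicate 3, 1 lower without siScr replicate 2, siScr replicate 3 or siAZIN1 replicate 3; adjusted p = 0.741), with the glycolytic enzyme gene PFKP lower by 0.58 on the log2 scale. Of 50 lysosome and autophagy genes 8 rose and 4 fell (11 and 6 when adjusted over the list alone, 5 higher without siAZIN1 replicate 2 or siAZIN1 replicate 3; adjusted p = 0.323), and MAP1LC3B, which marks autophagosomes, was 2.03-fold lower. Nuclear genes of oxidative phosphorylation gave 0 higher and 6 lower of 74 by edgeR (0 and 3 when adjusted over the list alone; 6 were higher at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom; adjusted p = 0.085), and mitochondrially encoded genes 0 and 2 of 15 (0 and 2 when adjusted over the list alone; 0 were higher at an unadjusted p under 0.05 and with DESeq2 or limma-voom; adjusted p = 0.177). The 2 lower mitochondrially encoded genes were MT-CO3 and MT-RNR1, and the size of the MT-RNR1 change rests on siScr replicate 1. Without that library both the oxidative phosphorylation and the mitochondrially encoded list passed, at 0.000126 and 0.00609. Without siAZIN1 replicate 2 the oxidative phosphorylation list did, at 0.00114. With a replicate block the mitochondrially encoded list passed, at 0.022, though the labels do not state that replicate numbers pair the libraries. The calls of both lists were lost with the correlation estimated from the data (adjusted p = 0.790 with an estimated correlation, 0.764 with it and without siScr replicate 1). Without siScr replicate 1, 18 oxidative phosphorylation genes, 5 mitochondrially encoded genes, 8 lysosome and autophagy genes and 10 genes of the endoplasmic reticulum list were lower, and without 1 of the other libraries as few as 3, 1, 3 and 2. Of the endoplasmic reticulum list 1 gene was higher without siScr replicate 1 and 2 were without siAZIN1 replicate 1, and 1 oxidative phosphorylation gene was higher without siScr replicate 3. Of 16 replication-dependent histone genes none passed by edgeR (0 also when adjusted over the list alone; 5 were lower and 0 higher at an unadjusted p under 0.05, 3 lower with DESeq2 and 0 with limma-voom). Their adjusted p was 0.200, and 0.0475 without siScr replicate 3, against an adjusted p of 0.790 with an estimated correlation and all libraries; 2 were lower by edgeR without siScr replicate 2 or siScr replicate 3. Of the genes named here, GDF15, MGST1, DDX21, CDKN2B, PFKP and MAP1LC3B, which fell, and TP53INP1 and SLC6A6, which rose, carry 1 or more of the 7 sequences found in an AZIN1 transcript. GDF15, MGST1, CDKN2B and TP53INP1 carry only the common TATTTAT.

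Some genes lower in siAZIN1 may be direct off-targets of the siRNA. Of 16232 7-mers in 3′ untranslated regions, 9 went with lower fold changes past Bonferroni, and the strongest, CATAGCA, had a t of −8.33. It lies in an AZIN1 transcript, as do 7 of the 9, against 29.8% of all 7-mers tested, though several of the 9 overlap and are not independent, and 6 of the 14 7-mers that went with higher fold changes, which an AZIN1 seed would not explain, lie in one as well. Of its 1233 carriers 18.6% were lower, against 11.7% of other genes (Fisher's exact test, two-sided p = 6.05e-11), and t was −4.53 and −7.27 in 2 random, separate parts of the genes. CATAGCA was picked over all these genes, so neither that p nor the 2 t values are independent support. The siRNA sequence is not given in the sources used here, so a seed match stays a candidate explanation, which covers at most part of the falls: 53.7% of lower genes and 45.4% of the others carry any of the 7 sequences.

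The fall of G1/S genes held its size among members without the sequences found. The 47 of 50 members without CATAGCA had a median log2 change of −0.406 (95% bootstrap interval −0.444 to −0.339). With so few carriers, leaving them out could hardly move the median. The 34 members without any of the 7 sequences had −0.399 (−0.429 to −0.324), and the 33 without any of the 9 −0.40 (−0.42 to −0.33). All lie beyond the bound of −0.205. For the members without them, this argues against silencing through these sequences in the longest 3′ untranslated region as the whole cause. The intervals resample genes, which are not independent, and not libraries. Leaving out siScr replicate 1 gave −0.400 (interval −0.454 to −0.336), and removing trends with GC content and transcript length −0.399 (−0.449 to −0.338), so these values argue against that library or such a trend as the whole cause. Direct silencing through other sequences or other parts of the transcripts stays open, and so does an indirect effect through an off-target gene or the fall of CCND1, as does a biological effect of AZIN1 loss. The 6 libraries allow 10 splits, too few for a share under 0.05: 1 split, the real one, called 3050 genes by edgeR and the highest other 0 (up to 1544 at an unadjusted p under 0.05).

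Sites of microRNAs classed as broadly expressed went with higher fold changes in siAZIN1. The strongest of 14 sequences that went with higher fold changes was TGGTGCT, the miR-29 site (t of 10.59; 19.98% of 2072 carriers were higher, against 9.72% of other genes), and sites of let-7, miR-27 and miR-15/16 passed too, but without covariates carriers of tissue-restricted sites were also higher more often (miR-124, 14.8% against 10.8%, with a t of −0.36). Sites of 26 families classed as broadly expressed lay above those of 13 classed as tissue-restricted (difference of median t 2.448). The permutation p was 2e-05, the smallest the draws can give, and the same without miR-29. That p treats the sites as independent. All their t values come from the same genes and libraries, and some sites overlap in sequence, so it can be too small. Weaker microRNA repression in siAZIN1 is therefore only a hypothesis, with no microRNA measured. An effect of the scrambled siRNA in the controls on the miR-29 site could give the same t of 10.59 and stays open. Of matrix genes, 23 with a miR-29 site had a median log2 change of 0.37 and 33 without it 0.10 (difference 0.2754, interval 0.0482 to 0.487, permutation p = 0.0248). Among the 23, 11 were called higher, and among the 33, 11. This comparison had no covariates for length or GC content. The matrix genes were also part of the scan that found the site, so it is not independent support. Leaving out siScr replicate 1 gave the matrix list a median of 0.2367 (interval 0.124 to 0.375), above the 0.159 with all libraries, which argues against that library as the source.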
